A study of Mus musculus with 4 samples.

How the data were processed

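4C DNA of ES cells and of embryoid bodies was measured on 4 custom NimbleGen tiling arrays of 50-base probes designed on mouse build mm6. Per the labels, the Cy5 channel held the amplified 4C product and the Cy3 channel MboI-digested genomic DNA of the same cells, on every array, so that no dye was swapped. Per the series' design text, the replicates were biological, each a pool of 3 independent samples. The deposited values are scanner intensity per probe and channel, extracted with NimbleScan per the file headers. Any correction of background or normalization made before deposit is not given in the sources used here, and the values showed none (the lowest lay well above 0 and medians differed between arrays). Both replicate 1 arrays were scanned on 1 day and extracted with NimbleScan 2.3.78, and both replicate 2 arrays on another day with NimbleScan 2.3.18, per the file headers. The 2 scan batches thus hold 1 ES and 1 EB array each and equal the replicate numbers.

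Each array had 389359 spots, of which 1193 random controls were left out of all tests, and 6 repeated tiling spots were averaged. For the tests fixed before the data were examined, log2(Cy5 / Cy3) of the intensities as given was centred on the median of each array's tiling probes, with no loess or quantile step. Values were the median over 10 kb windows with at least 5 probes, and the mean of window values over tiled regions with at least 10 probes. They were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 in a group means model over all 4 arrays, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences of 1 value per array were tested by exact permutation. Data were read with Python 3.11.15, pandas 2.3.3 and, in R, version 1.17.8 of data.table, and plots were drawn with matplotlib 3.10.9.

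Because the 4C channel of most probes lay at the level of the random controls, a second description was added after the data had been seen. The log2 Cy5 signal was centred on each array's median, a probe was positive at 1 log2 unit (2-fold) or more, and a run held at least 3 adjacent positive probes with gaps of at most 300 bp. A site was a run of probes each positive on at least 2 of the 4 arrays, whatever their group. Site means were tested with the same limma model. Runs expected by chance came from 20 random placements of the positive probes. Where both arrays of a group lay below the 2-fold level, the fold is a lower bound computed with that group at 1 log2 unit.

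Items named from the fixed tests were the 10 regions with the highest ratio among those past the threshold and above 0 on all arrays, the regions with the largest EB minus ES differences and non-overlapping arrays (up to 10 per direction past the threshold, otherwise filled to 5), and the highest window of chromosome 7. Sites are the 5 with the most probes per pattern outside the distal chromosome 7 region and the 3 within it. Alternatives were normexp background correction (offset 50), loess, scaling and quantile normalization, leaving out probes with dim input, other windows, the replicate block, robust eBayes, leaving out each array, and other site rules. Probes were counted as near the scanner's upper limit when their 4C signal lay within 2-fold of the highest value on any array, a check added after seeing the data.

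On simulated windows with the real means and spread (3785 windows, EB minus ES), limma recovered 16.0% of differences of 0.5 log2 units, 68.0% of 1, 96.0% of 2 and 96.0% of 4, with 5 false calls. For simulated sites (127 sites, EB minus ES), all 63 planted runs of 2 log2 units were called, 61 of 63 of 4 units and 3 of 64 of 1 unit. The planted shift was the same on both arrays of a group. Real sites positive on the ES arrays alone had medians of 2.88 and 4.38 log2 units on those arrays. Recovery of real sites may thus be lower than simulated. The replicate number pairs arrays through the scan day: deviations of the replicate 1 arrays from their group means correlated at 0.316 across windows and 0.755 across regions for the log ratio, and at 0.082 for the 4C channel.

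The lists of imprinted and other genes fixed beforehand were not tested, because an annotation of the build of the files was not used here; regions are named by position. The place of the bait within chromosome 7 is not given in the sources used here.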

Results

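Circular chromosome conformation capture (4C) was used to find the genomic fragments that lie close to 1 chosen locus, the bait, in the nucleus. The bait was the H19 ICR, the imprinting control region that governs the parent-of-origin expression of H19 and its neighbour Igf2 on distal mouse chromosome 7. 4C DNA from the mouse embryonic stem (ES) cell line R1 and from embryoid bodies (EB), the aggregates that form when ES cells differentiate in culture, was compared after 12 days of differentiation. Each of the 4 arrays, 2 for ES and 2 for EB, carried Cy5-labelled 4C product and Cy3-labelled input DNA of the same cells, and each replicate was a pool of 3 samples. The array carried 388160 tiling probes, for locations that the submitters chose from an earlier genome-wide 4C screen, and 1193 random control probes. Of the tiling probes, 344020 lay in 26 tiled regions of at least 800471 bp, 39835 in 97 regions of about 40 kb, and 4305 had no region label. All coordinates are those of mouse build mm6. The number of arrays limits the precision of every value below.

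The 4C product bound few of the tiled probes. The median 4C signal of the tiling probes was 969 intensity units on ES replicate 1, 1521 on ES replicate 2, 543 on EB replicate 1 and 1638 on EB replicate 2. Random control probes had medians of 963, 1481, 534 and 1607 on the same arrays. The 95th percentile of the 4C signal was 1.77, 1.89, 1.59 and 1.87 times the 5th percentile, against 16.8, 11.6, 19.9 and 6.99 times in the input channel. Signal at least 2-fold over the array median was therefore counted as 4C-positive, and runs of at least 3 adjacent positive probes were taken as 4C signal. This rule was chosen after seeing the data.

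By this rule, 4C signal in ES cells was concentrated in the most distal tiled region of chromosome 7 (136488552 to 138655803), the chromosome of the bait. There 8.50% ± 1.71 (SD, n = 2) of the probes lay in runs in ES and 0.892% ± 0.039 (SD, n = 2) in EB. Within the first replicate the shares were 7.29% in ES and 0.864% in EB, and within the second 9.71% and 0.919%. With 2 arrays against 2, an exact permutation test cannot go below p = 0.33. The ratio test fixed beforehand did not place this region as a whole above the array median. Its mean log2 ratio of 4C to input was -0.0485 in ES (limma adjusted p = 0.578) and -0.154 in EB (limma adjusted p = 0.139). That test averages medians of 10 kb windows, which signal in a small share of the probes hardly moves. The other 25 large regions held 0.0156% ± 0.0042 of their probes in runs in ES and 0.0121% ± 0.0078 in EB (SD, n = 2). Small regions held 0.0339% ± 0.0231 in ES and none in EB, and 94 of the 97 small regions had no run on any array. Of the other 25 large regions, 12 had no run on any array.

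**Figure D1:**
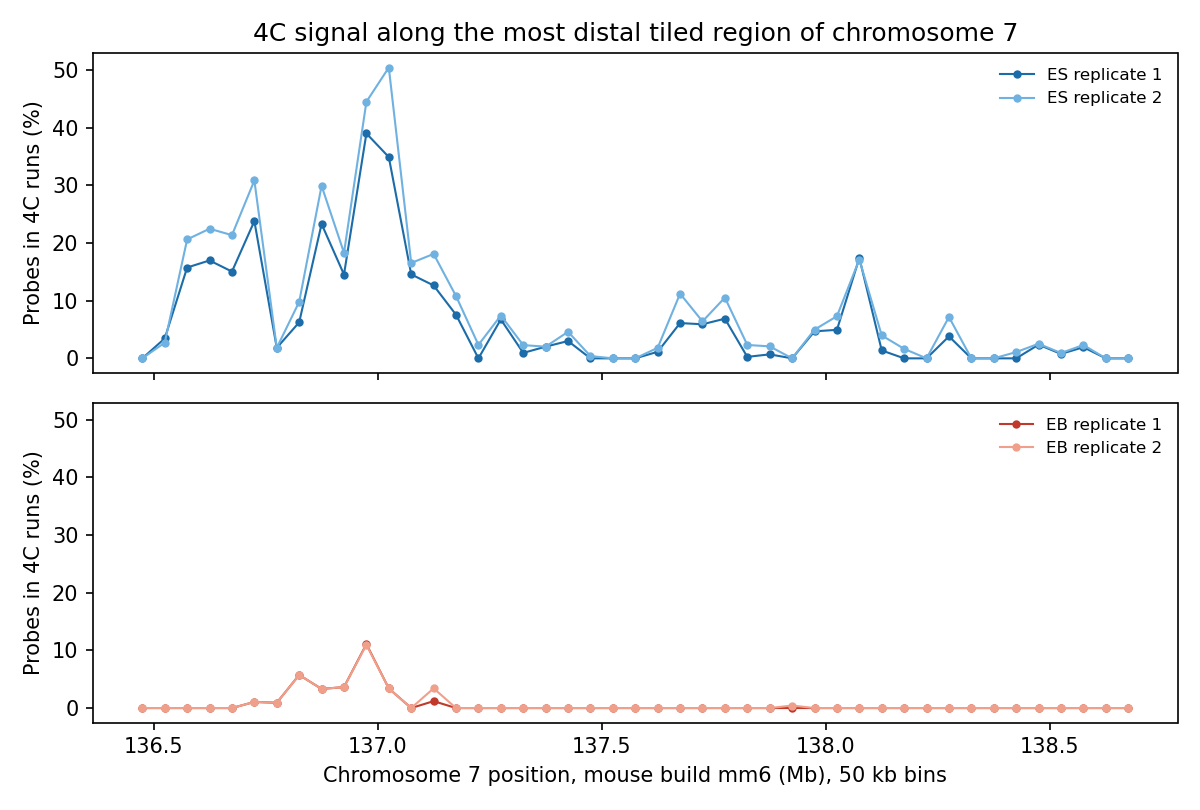
Share of probes in 4C runs (percent, vertical axis) in 50 kb bins along the most distal tiled region of chromosome 7 (horizontal axis, Mb, build mm6), with 1 line per array, ES above and EB below. Both ES arrays peak between 136950001 and 137050000, where ES means reach 41.8% and 42.7%, and the EB peak of 11.04% falls in the first of these bins.

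The bin with the highest share lay between 136950001 and 137050000 in both cell states. The 50 kb bin from 136950001 to 137000000 held 41.8% ± 3.88 of its probes in runs in ES and 11.04% ± 0.083 in EB (SD, n = 2). In the next bin the shares were 42.7% ± 10.98 in ES and 3.40% in both EB replicates. Across the 45 bins the ES and EB means correlated with Pearson's r = 0.666 (permutation p = 1e-04, the smallest that 10000 permutations can give) and Spearman's rho = 0.436 (permutation p = 0.0017). These are correlations across neighbouring bins, which are not independent replicates. The EB mean was 0 in most bins, and below the peak of 11.04% the next highest was 5.74%, so that Pearson's r leans on few bins. In 32 of the bins both ES arrays lay above both EB arrays, and in 0 bins the reverse held. ES arrays also had runs farther along the region, such as 17.3% ± 0.187 of the probes from 138050001 to 138100000 (SD, n = 2), where both EB arrays had 0. The highest 10 kb window of chromosome 7, from 136990001 to 137000000, had log2 ratios of 4C to input of 4.31 and 5.19 in ES and 4.02 and 4.31 in EB.

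Joining probes that were positive on at least 2 of the 4 arrays gave 268 sites, against a mean of 1.35 when the positive probes were placed at random. Of these, 231 were positive on both ES arrays and on no EB array, 26 on both EB arrays and on no ES array, and 9 on all 4 arrays. The remaining 2 had other combinations, 1 of them being both arrays of a scan batch alone. After normexp background correction of the 4C channel, 396 sites were positive on both replicate 2 arrays alone, which shared a scan batch. A further 299 were positive on both arrays of a cell state alone and 12 on pairs that shared neither. Of the 257 sites found in 1 cell state alone, 219 kept their pattern when the same probes were read after normexp. The test with limma called 232 sites higher in ES and 29 higher in EB (Benjamini-Hochberg adjusted p under 0.05, 2 arrays per group). Sites were selected on the same values, most of them through the 1 state where they were high, so that these calls largely follow from the selection. The adjusted p-values of sites, here and below, are not separate evidence of a difference. They rest on the spread between 2 replicates that shared nearly all probes in runs. With the replicate as a block, which is also the scan batch, 261 sites were called, 260 of them in both fits. Leaving out EB replicate 1 or EB replicate 2 lowered the sites called higher in ES to 109 and 122.

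**Figure D2:**
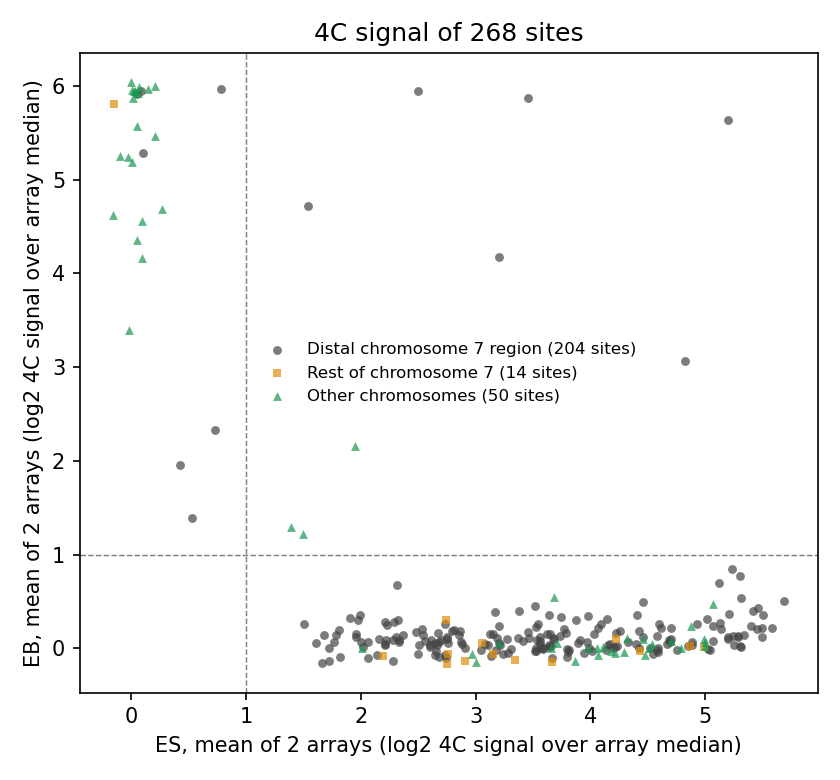
Mean 4C signal of each of the 268 sites in ES (horizontal axis) and EB (vertical axis), in log2 units over the array median, 2 arrays per mean. Dashed lines mark the 2-fold level, and symbols give the location of the site. Most of the points lie along the 2 axes, with 231 sites positive on both ES arrays alone and 26 on both EB arrays alone.

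ES-only sites lay mostly in cis, on the bait's own chromosome, and EB-only sites mostly in trans. Of the 231 ES-only sites, 204 were on chromosome 7 and 27 on 11 other chromosomes. Of the 26 EB-only sites, 6 were on chromosome 7 and 20 on 12 other chromosomes. The odds ratio was 24.6 (95% confidence interval 8.61 to 81.8, Fisher's exact test over sites, two-sided, p = 3.685e-12). EB-only sites leave out the chromosome 7 sites that EB shared with ES. Of all probes in runs, 93.0% ± 1.74 in ES and 70.7% ± 2.44 in EB (SD, n = 2) lay on chromosome 7. These shares depend on the array, which put 26974 probes in the distal region. Outside chromosome 7, 3190 probes without a region label lay at 2185 loci. Of the sites on all 4 arrays, 6 were on chromosome 7 and 3 elsewhere, and the 2 of other combinations were on chromosome 7. Whether most EB signal was in cis thus depended on counting probes or sites. Sites of 1 neighbourhood are not independent, and Fisher's test covers these 4 arrays only. The median signal of the ES-only sites was 2.88 and 4.38 log2 units on the ES arrays and 0.042 and 0.12 on the EB arrays. EB-only sites had medians of 6.30 and 5.06 on the EB arrays and 0.025 and 0.084 on the ES arrays. With the dimmer group set at the 2-fold detection level, ES-only sites were at least 1.42- to 25.7-fold higher in ES (median 6.28), and EB-only sites at least 1.94- to 32.9-fold higher in EB (median 25.9). The scanner's upper limit lay 6.08 and 5.43 log2 units above the array median on the ES arrays and 6.92 and 5.32 on the EB arrays, so that signal above these levels cannot be seen.

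The longest site lay on chromosome 7 from 136992893 to 136997518 (119 probes). It was positive on all 4 arrays, and whether it holds or flanks the bait is not known. Its signal was 5.15 and 5.24 log2 units over the array median in ES and 6.31 and 4.97 in EB, and 71.4%, 99.2%, 84.0% and 93.3% of its probes lay within 2-fold of the upper limit, so that no difference between the states can be read there. Directly beside it, the site starting at 136997915 (98 probes) had 5.29 and 5.18 in ES and 0.91 and 0.77 in EB, at least 18.8-fold higher in ES (limma adjusted p = 0.00086). These are means over a mixed site, since 10 of its 98 probes lay within 2-fold of the upper limit on each EB array, while the probe medians in EB were 0.18 and 0.28. Of the 231 ES-only sites, 1 held probes in runs on an EB array, and 0 of the 26 EB-only sites held probes in runs on an ES array. Other long ES-only sites of the region started at 137029024 (58 probes, at least 11.9-fold, adjusted p = 0.0012) and at 136978409 (54 probes, at least 9.15-fold, adjusted p = 0.0028, both limma). A site of 46 probes starting at 136948151 was positive in both states and higher in EB, with 1.10 and 1.97 log2 units in ES and 4.75 and 4.70 in EB (limma adjusted p = 0.0032). It was mixed in ES, with probe medians of 0.68, under the 2-fold level, and 1.56. Near the upper limit lay 0% and 17.4% of its probes in ES and 17.4% and 78.3% in EB. A site of 49 probes starting at 137012702 was positive in both and had a lower mean in EB, with 4.65 and 4.995 log2 units in ES and 3.41 and 2.72 in EB (limma adjusted p = 0.016). Its signal was not uniformly lower, since 53.1% and 93.9% of its probes in ES and 48.98% and 51.02% in EB lay within 2-fold of the limit, with probe medians of 5.13 and 5.21 in ES and 5.06 and 4.57 in EB. This last call was lost without EB replicate 1 (adjusted p = 0.086) or without EB replicate 2 (adjusted p = 0.17). Within the same neighbourhood the embryoid bodies had sites that ES lacked, starting at 136857649 (21 probes, at least 30.2-fold), 137019571 (19 probes, at least 19.6-fold) and 136848367 (13 probes, at least 30.8-fold). The sites named here and below were chosen by length after their values were seen.

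Outside chromosome 7, all 20 EB-only sites fell on probes with no region label. The longest was on chromosome 17 from 47361542 to 47363142 (17 probes), with 5.66 and 4.83 log2 units in EB and -0.019 and -0.026 in ES, at least 18.9-fold higher in EB (limma adjusted p = 0.00086). Others lay on chromosome 14 at 92417482 (at least 9.00-fold) and 82391871 (at least 31.2-fold) and on chromosome 15 at 64284904 (at least 23.7-fold). Of the 27 ES-only sites outside chromosome 7, 22 fell on probes with no region label. The longest started at 37126182 on chromosome 12 (12 probes), with 2.99 and 5.12 log2 units in ES and 0.078 and -0.082 in EB, at least 8.33-fold higher in ES (limma adjusted p = 0.0071). A second neighbourhood of chromosome 12, from 103989051 to 104184740, held 3 ES-only sites, of which the first was at least 6.29-fold higher in ES (limma adjusted p = 0.0078). ES-only sites also lay on chromosome 14 at 69359036 (at least 9.28-fold) and on chromosome 18 at 52382929 (at least 7.30-fold). The calls of the first chromosome 12 site of that neighbourhood and of the chromosome 18 site were lost when either EB array was left out (adjusted p from 0.053 to 0.062).

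Replicates shared more of their probes in runs than the cell states did. ES replicate 1 had 2497 probes in runs and ES replicate 2 had 3391, of which 2470 were shared, and EB replicates 1 and 2 had 443 and 497, of which 429 were shared. Between an ES and an EB array, 40.2% to 52.4% of the smaller set was shared, and outside chromosome 7 4.55% to 9.02%. In the distal region such pairs shared 140 to 163 probes, but 58 to 80 once the longest site was left out. Across 10 kb windows, Pearson's r of the 4C channel was 0.918 between the ES arrays and 0.968 between the EB arrays, against 0.057 to 0.127 between an ES and an EB array. Spearman's rho did not follow that order, with 0.368 and 0.436 between replicates and 0.262 to 0.653 between an ES and an EB array. For log ratios of 4C to input, Pearson's r was 0.886 between the ES arrays, 0.896 between the EB arrays, 0.798 and 0.580 within a scan batch, and 0.643 and 0.667 between arrays that shared neither. Spearman's rho was 0.890 and 0.885 between replicates and 0.904 and 0.906 within a scan batch, and Pearson's r over single probes was 0.799 and 0.805 between replicates and 0.845 and 0.853 within a scan batch. Whether cell state or scan batch grouped the ratios more closely thus depended on the measure. These correlations are across windows or probes, which are not independent replicates.

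The tests of the ratio of 4C to input, fixed before the data were examined, called many windows against the array median and few between the cell states. Of 3785 windows of 10 kb, limma called 842 above and 843 below the array median in ES, and 645 above and 659 below in EB (Benjamini-Hochberg adjusted p under 0.05). These counts fell to 24 above in ES and 11 in EB with loess, and to 32 and 14 without the probes of dim input. Without those probes the ratios stayed centred on the median of all tiling probes. Windows of dim input tended to have high ratios, so that leaving dim probes out lowers the counts in itself. Only 38 of the 842 higher windows in ES and 14 of the 645 in EB had a mean log2 ratio of at least 1. Among the windows with the highest 5% of ratios, 189 in each state, 133 were shared, against 9.44 for independent lists. The lists are not independent, since the input channel of ES and EB arrays correlated across windows at Pearson's r of 0.918 to 0.971. The overlap was smaller with loess, and it is not a count of shared contacts. Between the states 16 windows differed, 10 higher in EB and 6 higher in ES. The split by direction depended on the processing. With normexp 11 were higher in EB and 28 in ES, with quantile normalization 11 and 16, with loess 9 and 9, and with scaling 0 and 1. Over all 3785 windows, 1622 had the same direction within both scan batches. With the replicate block 51 differed, 12 higher in EB and 39 higher in ES. The window on chromosome 8 from 59920001 had log2 ratios of 5.58 and 5.59 in EB and -0.56 and -0.83 in ES (limma adjusted p = 1.27e-05). The window on chromosome 1 from 146640001 had 4.89 and 6.19 in ES and -0.48 and 0.23 in EB (limma adjusted p = 0.0038), and that on chromosome 7 from 109350001 had 4.83 and 5.68 in ES and -0.065 and 0.11 in EB (limma adjusted p = 0.00065). In the state with signal, 37.5% to 100% of the probes of these 3 windows lay within 2-fold of the scanner's upper limit, and the differences are not ranked by size.

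Over whole tiled regions, limma called 41 of 123 above and 30 below the array median in ES, and 1 above and 11 below in EB. With the replicate block, EB had 48 above and 32 below. No region differed between the states by limma (0 of 123, with 0 at an unadjusted p under 0.05; with the block 0, and 2 at an unadjusted p under 0.05), but 6 were called when EB replicate 1 was left out. Region values are means of window medians, so that 4C signal in a small share of the probes hardly moves them. The distal region of chromosome 7 had EB minus ES of -0.105 (limma adjusted p = 0.996) despite its difference in runs. The lack of called regions thus does not speak against differences in runs. The 10 regions with the highest ratios, on chromosomes 1, 4, 5, 6, 9, 15, 16, 19 and X, had means over the 4 arrays of 0.42 to 0.64 log2 units. When the probes with the dimmest 20% of input signal were left out, 9 of the 10 turned negative in ES (-0.0503 to -0.658) and in EB (-0.0059 to -0.409), and 0 of the 123 regions were called above the array median in either state. The ratios were not centred anew in that setting. Across windows, ratio and input correlated at -0.759 to -0.882, so that leaving out dim probes lowers the remaining values in itself. The first of the 10 regions was on chromosome X from 59028424 to 59068493, with 0.81 and 0.58 in ES (limma adjusted p = 0.037) and 0.87 and 0.30 in EB (limma adjusted p = 0.055). Of the 123 regions, 12 had both EB arrays above both ES arrays and 7 had both below, fewer than the 33.3% of regions that a random order of the arrays would give. None passed the threshold. They included chromosome 7 from 39962317 to 40002442 (EB minus ES 0.22 ± 0.09, SE) and chromosome 11 from 17016222 to 17056295 (EB minus ES -0.11 ± 0.07, SE), both with limma adjusted p = 0.996.

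To set contacts on the bait's chromosome against contacts elsewhere, the mean window ratio of chromosome 7 was taken relative to that of the other chromosomes. It was higher by 0.119 ± 0.006 log2 units in ES and by 0.0454 ± 0.0037 in EB (SD, n = 2). The EB minus ES difference was -0.0739 (exact permutation test, two-sided, p = 0.33, the smallest that 2 against 2 arrays can give). Within the scan batches it was -0.0723 and -0.0754. Neither the excess of chromosome 7 nor its difference can be read as contacts in cis. Of its 875 windows, 388 lay in the region from 52536661 to 56638685, with mean ratios of 0.292 in ES and 0.246 in EB. That region held 2 and 2 probes in runs in ES and 3 and 0 in EB. The distal region held 1967 and 2618 in ES and 233 and 248 in EB, yet had mean ratios of -0.0485 and -0.154.

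**Figure D3:**
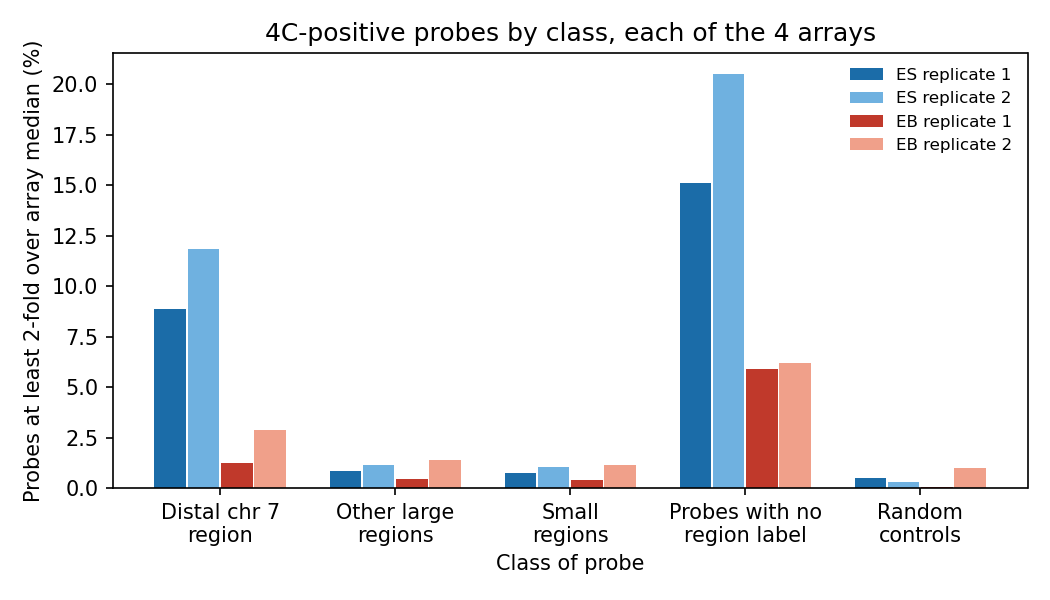
Percent of probes with 4C signal at least 2-fold over the array median (vertical axis) by class of probe (horizontal axis), with 1 bar per array. Distal chromosome 7 reaches 8.87% and 11.8% on the ES arrays against 1.28% and 2.90% on the EB arrays, and the random controls lie between 0.0838% and 1.01%.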

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

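The tests of the overlap within bins and of the probes in runs on a single replicate were planned before their results were seen; the others in this part were chosen only after.

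Probes without a region label, which the region tests do not use, held a larger share of 4C-positive probes than any of the other classes of probe taken as a whole, although single 50 kb bins of the distal region reached 42.7% of probes in runs in ES. On average 17.8% ± 3.83 of them in ES and 6.05% ± 0.21 in EB (SD, n = 2) were at least 2-fold over the array median, against 0.419% ± 0.119 and 0.545% ± 0.652 of the random controls. On chromosome 7, 38.2% ± 6.21 of 1115 such probes lay in runs in ES and 7.80% ± 0.25 in EB. On other chromosomes the shares were 5.09% ± 2.50 and 3.26% of 3190 probes.

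The window ratios varied alike on all 4 arrays. The input channel accounted for 57.6% to 77.7% of their variance, but the ratio contains the input, and independent channels of the same spread would give 64.3% to 82.99%. Input hybridisation under a 4C channel near background and contacts shared by both cell states cannot be told apart from these values. The 4C channel correlated across windows at no more than 0.127 between an ES and an EB array by Pearson, but by rank at 0.262 and 0.653 within the batches and at 0.323 and 0.411 across them, against 0.368 and 0.436 between replicates.

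The sites differed between ES and EB. Each scan batch held an ES and an EB array, so that a batch alone would give as many sites on both arrays of a cell state as on pairs sharing neither state nor batch. As the source of the sites of 1 state it is argued against by 257 against 0 such sites, and by 299 against 12 after normexp. State pairs were more numerous on 17 chromosomes and on 20 after normexp, and on 0 the reverse held (exact sign test p = 1.5e-05 and 1.9e-06). All chromosomes were read from the same 4 arrays, so that these p-values do not measure the spread between replicates. A scan batch remains open for the 396 sites that normexp put on the replicate 2 arrays alone, and 219 of the 257 sites kept their pattern after normexp. A uniform loss of 4C signal on the EB arrays cannot give the 26 EB-only sites. For the ES-only sites, such a loss alone would keep the distal sites that are brighter in ES. A kept site was brighter than a lost one in a share of 0.459 of pairs (6 kept and 191 lost sites). The bootstrap 95% interval, over the kept sites alone, was 0.209 to 0.713. However, the kept sites starting at 136739067, 136799951 and 136948151 were themselves higher in EB, by 3.45, 2.42 and 3.19 log2 units. They need not be sites that a loss spared, so that the share cannot decide against a loss joined by gains in EB. Whether each 4C product sampled few fragments of a shared neighbourhood cannot be told apart: outside the longest site, the overlap of ES and EB runs exceeded that of 1000 circular shifts within 50 kb bins on 3 of 4 pairs of arrays (permutation p = 0.013 to 0.024), and on the fourth the permutation p was 0.05. Differentiation itself stays open and untested.

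Replicate arrays of a cell state shared 98.9% and 96.8% of the smaller set of probes in runs, while the larger sets held 921 probes in ES and 68 in EB that were in runs on that array alone. Of the probes in runs on 1 replicate alone, 71.8% in ES and 85.4% in EB lay above the 95th percentile of the random controls on the other replicate. This is in line with 1 amplified product hybridised on both arrays, but contacts repeated in separately prepared pools, as the design text describes, would give it as well. The tables do not decide between them.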

How the results depend on the processing

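The alternatives for the ratio tests were fixed before the data were examined; those for the sites, the bins and the share of the distal region were chosen after seeing the data. Pairing arrays by number, the replicate block gave 1105 windows above the array median in ES, 964 in EB and 51 differing (without it 842, 645 and 16), and 52, 48 and 0 regions (without it 41, 1 and 0). Among the sites it called 231 higher in ES and 30 in EB.

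Counts over input depended on how the input channel was handled. Without dim input probes the ratios were not centred anew, which lowers the counts in itself. Leaving out dim input probes left 32 windows in ES and 14 in EB and 0 regions in each; loess left 24, 11 and 0, 96.0% and 100% of the window calls being higher, against 49.97% and 49.5% without loess. With normexp 34 regions were above in EB and 39 windows differed. Scaling gave 1011 windows and 46 regions in EB and 1 window differing; quantile normalization 1052, 48 and 27; robust eBayes 997, 41 and 52. Window means gave 17 regions in ES, 14 in EB and 33 windows differing. Windows of 5 kb gave 1552 in ES, 1217 in EB, 37 differing and 13 regions in EB. With 50 kb the values were 223, 13 and 33 regions in EB, the number of windows tested being changed in both. With at least 10 probes 2 windows differed. Leaving out 1 array gave 131 to 1004 windows in ES, 12 to 813 in EB and 9 to 46 differing, and 0 to 47, 0 to 45 and 0 to 6 regions; without EB replicate 1, 12 windows were above in EB and 6 regions differed. The lone array of a group is then assumed to vary like the other group. The cause of these shifts was not tested except where named.

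Chromosome 7 minus other chromosomes kept its sign, EB minus ES being -0.107 with normexp, -0.0623 with scaling, -0.0593 with quantile normalization, -0.0882 without dim probes, -0.0978 with window means, -0.0801 with 5 kb, -0.114 with 50 kb, -0.0642 with at least 10 probes and -0.0677 with the median. The mean Pearson correlation of window ratios within a cell state lay 0.219 above that between states, but only 0.00934 above by Spearman, and over single probes it was reversed (-0.00514, Pearson). These 2 measures were added after seeing the data. By Pearson over windows the gap was 0.856 with loess, 0.583 with 50 kb and 0.0417 with at least 10 probes. Shared highest windows were 53 with loess, 229 with 5 kb, 19 with 50 kb, 6 in the top 1% and 300 in the top 10%.

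With sites of at least 5 adjacent probes, 151 were higher in ES and 16 in EB, as fewer sites qualify. Leaving out 1 array gave 109 to 233 higher in ES and 26 to 28 in EB. After normexp 396 sites were positive on ES replicate 2 and EB replicate 2 alone, the brighter scan batch, while 243 sites were called higher in ES and 31 in EB. With a 4-fold threshold the EB minus ES share of distal probes in runs was -5.68 percentage points, against -7.61. The odds ratio of the chromosome 7 sites was 19.1 to 33.7 and the correlation over bins 0.550 to 0.744. The sign of the longest site on all 4 arrays, not called, turned without EB replicate 1 (-0.227, against 1.11 without EB replicate 2), but most of its probes lie within 2-fold of the scanner's upper limit on every array, so that neither sign is a result.

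Of the named regions, the log2 ratios that changed sign without dim input probes were -0.338, -0.658, -0.137, -0.0503, -0.111, -0.257, -0.113, -0.232, -0.206 in ES and -0.356, -0.409, -0.183, -0.014, -0.198, -0.225, -0.0059, -0.287, -0.206 in EB, and with loess -0.00204 in ES and -0.018, -0.0056 in EB. Of the region differences, none called, EB minus ES changed sign to -0.021, -0.0054, 0.018 with loess, 0.017, 0.0014, 0.032, 0.0898 without dim probes, 0.00597 with window means and 0.039, 0.029 with 50 kb. Signal over background limits all of these, since most 4C probes lie at the level of the random controls. The changes of sign in ES and in EB without dim input probes can also follow from ratios that were not centred anew.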

Other observations

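Most sites outside chromosome 7 stood alone: within 1 Mb of each other, the 20 EB-only sites formed 15 groups and the 27 ES-only sites 24, of which 3 and 2 held more than 1 site. Embryoid bodies had 4 sites on chromosome 13 within 522 kb (62894767 to 63417112), with mean 4C signals of 5.05 and 4.38 log2 units in EB and 0.17 and -0.0091 in ES. That stretch was not silent on ES replicate 2. There 2 probes in each of the 10 kb windows from 62890001, 63030001 and 63270001 lay within 2-fold of the scanner's upper limit, against 0 on ES replicate 1. Embryoid bodies also had 2 sites on chromosome 17 within 331 kb (47032193 to 47363142), with 6.08 and 5.03 in EB. ES cells had 3 sites within 196 kb on chromosome 12. On chromosome 7 outside the distal region, 13 of 14 sites were positive on both ES arrays alone, from 19860354 to 139427051, and 1 at 115998055 on both EB arrays alone (6.36 and 5.27 in EB, -0.13 and -0.17 in ES). Beyond the distal end of the tiled region ES had sites at 139060160 and 139425860.

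3 weak sites on chromosomes 6, 9 and 15 were positive on all 4 arrays. The one on chromosome 15 from 73003638 (11 probes) had 1.47 and 1.31 log2 units in ES and 1.40 and 1.19 in EB.

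Since the small regions span about 40 kb each, a hypothesis was that each was centred on a fragment of the earlier screen and that 4C signal may lie at its centre. The test was planned before its result was seen. In the central 1 kb of the 97 regions 0.812% of the probes were positive on both ES arrays, 0.541% on EB replicate 1 and 1.08% on EB replicate 2. All 4 shares lay within the central 95% of 1000 random positions, so that no excess at the centre was found. Since 94 of the 97 regions had no run on any array, there was little 4C signal whose place could be tested.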
